A study of Homo sapiens with 2 samples.

How the data were processed

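For the labelled samples, live CD45-positive and CD45-negative tumour cells were mixed 8 to 2, stained with 137 TotalSeq-C antibodies and loaded for 10x Genomics 5′ chemistry (version 1.1), per the labels' protocols. Their stated mean depth was 42000 RNA, 34000 T cell receptor and 5700 antibody reads per cell. The series description says that the earlier samples were sequenced and processed alike, and whether their cells were mixed in that ratio is not given in the sources used here. The deposited matrices hold UMI counts per gene or antibody tag and barcode, not normalized, with 36601 genes and 137 antibodies, as filtered by the submitters' pipeline. Cell Ranger 4.0.0 and the mouse build mm10 are named for the labelled samples, per the submitters' processing notes, but the gene identifiers in the matrices are human, so the build behind these counts is not given in the sources used here. Gene symbols were taken from the matrices' own feature tables. The 2 labelled samples have no count table among those used, and both matrices were re-made by the submitters from earlier samples, per the series description. T cell receptor sequences were not analysed here. The 2 matrices shared 43 barcodes by sequence.

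Barcodes with fewer than 300 genes (25 in the single-donor library, 82 in the pooled library) or more than 15% mitochondrial UMIs (68 and 23) were removed, which left 2305 and 9845. Scrublet, as in scanpy, marked 6 and 2 of these (0.260% and 0.0203%), which were removed, leaving 2299 and 9843 cells. The caller is taken not to have worked in the pooled library, where it marked under 0.5% of more than 5000 cells, so doublets remain there and in part in the single-donor library.

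Each matrix was analysed alone. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 components were taken, and cells were clustered with Leiden at resolution 1 on 15 neighbours. Clusters were called by markers of T, NK, B, plasma, monocyte or macrophage, dendritic, plasmacytoid dendritic, mast, neutrophil, epithelial, fibroblast, endothelial, mural and erythroid cells, and no cluster was named neutrophil or erythroid. A cluster took the class with the highest mean log2 ratio of its markers' CPM to the lowest cluster's CPM, with 50 CPM added to both, or the class scored next within 1 of it where that one had more markers among the 10 leading genes. It stayed unnamed with fewer than 3 markers detected in at least 5% of its cells, a best score under 1, or more markers of another class among its 10 leading genes. T-like and NK-like cells, with any unnamed cluster scoring best for them, were clustered again without the genes of the tested lists, CD69 and T cell receptor genes, and named by markers of CD8, CD4, regulatory T and NK cells. A CD8 cluster was exhausted-like if at least 5 of 10 exhaustion markers (PDCD1, HAVCR2, LAG3, TIGIT, CTLA4, ENTPD1, TOX, LAYN, CXCL13 and TNFRSF9) were at least 1.5 times as high as in the other CD8 T-like cells. In the single-donor library 1 cluster of 89 cells met 9 markers, and in the pooled library 1 cluster of 350 cells met 6.

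The filters, markers, lists, comparisons, the exhausted-like rule, the rule for named genes and a first set of alternatives were fixed before the data were examined. Several choices came later. The score that turned markers into cluster names was revised after its first version had been seen. The requirement that CD8 clusters have a higher median CD8 than CD4 antibody count was set after the values had been seen. Altogether 3 forms of the exhausted-like rule were tried. The rule as first written gave the reported results, and the others, in which clusters were added one at a time with or without a minimum of 10 UMIs per marker, are alternatives. Also added later were removal of doublets at the expected rate (0.8% per 1000 cells), an antibody gate on CD8 clusters (at least 10 CD8 antibody counts per cell and 2 times the CD4 counts), removal of CD8 clusters led by stress, metallothionein or cycling genes or of low UMI counts, and the CD69 share of antibody counts for the quadrants.

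Summed counts of 2 groups of cells were compared as ratios of CPM (each gene's UMIs over the group's total UMIs, times 1e6) with exact conditional binomial intervals (95%). A group at 0 gives a bound from a floor of 3 counts over the group. The 10 tested lists were cytotoxic, cytokine and chemokine, naive and memory, residency, early response to T cell receptor signals, interferon response, cycling, glycolysis, oxidative phosphorylation and heat shock genes. A list's median log2 ratio was given an interval from 1000 Poisson redraws. It was also given a percentile among 10000 random lists of the same size matched on mean expression, as a description of these libraries. The percentile compares lists of genes over the same groups of cells and does not cover variation between cells. For the CD69 split, each exhausted-like cell was thinned at random to 1500 UMIs. Antibody counts were compared as shares of all antibody counts of the group, and 118 of 137 antibodies were matched to a gene by gene identifier.

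By the rule for named genes, list members needed 20 UMIs summed over both groups in each library, and the 2 with the largest and the 2 with the smallest ratio per list could be named (up to 4), with CD69, CD8A, CD8B and the exhaustion markers. For the CD69 split and the comparison of libraries, the 10 genes outside the lists with the largest ratio in each direction and at least 50 UMIs were added. Genes of the Y chromosome, XIST, immunoglobulin, T cell receptor and HLA genes were never named. This rule picked 42 genes for the first comparison, 54 for the CD69 split and 68 for the comparison of libraries. After a first table of the alternatives had been seen, the genes that could be described were narrowed to picks at least 1.5 times apart in the same direction in every library, plus CD69, CD8A and CD8B, which left 18, 8 and 59, and quadrant results were narrowed to the cytotoxic and cytokine lists. This narrowing left out many values that changed sign under other settings: over all picks 1188 of 6092 alternative log2 values lay on the other side of 0 from the reported one, and 368 turned sign where the reported interval excluded 0. A higher threshold for the comparison of libraries was tried and dropped.

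The procedure was tested on simulated counts drawn from the real group means and library sizes, with 200 changed genes each. In exhausted-like against other CD8 T cells it recovered 50% of 2-fold and 80% of 4-fold changes among 6050 genes of the single-donor library and 63% and 86% among 10789 genes of the pooled library. In the CD69 split it recovered 43% and 74% among 749 genes, and 55% and 88% among 2342 genes. Between the libraries it recovered 70% and 89% among 4784 genes. Intervals covered the true ratio for 96.5% to 97.1% of genes. The draws were Poisson, the model that the intervals assume, so this coverage was set by the design. Variation between cells or donors was not simulated, and coverage and recovery in the real data can be lower.

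The alternatives covered cell filters, doublets, clustering resolution, the number of variable genes, the minimum count, TMM factors from edgeR 4.0.16 on the summed counts, a gate on single cells in place of clusters (CD8A or CD8B, no CD4 and 3 or more exhaustion markers), thinning depth and the number of CD69 UMIs. Software was Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3.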

Results

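The data were droplet-based single-cell profiles of human tumour cells in which RNA and 137 surface antibodies were counted in the same cell (CITE-seq, where each antibody carries a DNA tag that is sequenced with the transcripts). The labels describe 2 samples of primary head and neck tumours, whose own count tables were not analysed here. The 2 count matrices used come from earlier samples that the submitters re-analysed for the same study, 1 named for a single donor and 1 for a pool of donors with no map from cells to donors. Both are described as enriched for CD45-positive cells, and the protocol of the labelled samples mixed sorted CD45-positive and CD45-negative cells 8 to 2. Whether the earlier samples were mixed in that ratio is not given in the sources used here. Each matrix is therefore 1 sample, no difference below has a replicate check, and no statistical test across samples was made. Groups of cells compared within the pooled library can hold different shares of its donors. A difference between donors cannot be told apart there from a difference between the groups. The title of the series names effector function among exhausted CD8 T cells, which are T cells held in a dysfunctional state by lasting antigen, and the study separated cells by CD69, an early activation antigen.

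The single-donor library held 2394 barcodes with 5145334 RNA UMIs and 15854176 antibody counts, and a median of 1829.5 UMIs and 786 genes per barcode. The pooled library held 9940 barcodes with 29097723 RNA UMIs and 28414378 antibody counts, and a median of 1958 UMIs and 935 genes. The median antibody count per barcode was 5594 in the single-donor library and 1985.5 in the pooled library. In the filtered cells, mitochondrial genes took a median of 3.97% of the UMIs in the single-donor library and 0.624% in the pooled library. Gene levels are UMIs of a gene scaled to the total UMIs of the group of cells (CPM), and ratios are ratios of CPM. Intervals below are exact 95% Poisson or binomial intervals and cover counting error only.

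T-like cells were the largest class in both libraries. They made up 1820 of 2299 cells of the single-donor library (79.2%, interval 77.4 to 80.8) and 6384 of 9843 cells of the pooled library (64.9%, 63.9 to 65.8). The single-donor library also held mast-like cells (111, 4.83%), B-like cells (108, 4.70%), a cluster that took the plasma-like name by its markers (44, 1.91%), and 216 cells (9.40%) in a cluster that stayed unnamed. Its mast-like cluster was also led by XCL1, XCL2 and AREG, genes that NK cells express, and scored 2.71 for mast and 2.28 for NK cells. Among the leading genes of its plasma-like cluster, those that myeloid cells express (CST3, CXCL8, IL1B, IFI30 and CFD) outnumbered those of plasma cells (DERL3, JCHAIN and MZB1), so it is a mixed cluster. No cluster of it was named as a non-immune class. The pooled library held fibroblast-like (589, 5.98%), monocyte or macrophage-like (586, 5.95%), mast-like (565, 5.74%), NK-like (511, 5.19%), endothelial-like (197, 2.00%), mural-like (197, 2.00%), plasma-like (159, 1.62%), dendritic-like (147, 1.49%), B-like (138, 1.40%), plasmacytoid dendritic-like (64, 0.650%) and epithelial-like cells (53, 0.538%), with 253 cells (2.57%) unnamed. Named immune classes made up 90.6% of the single-donor library and 86.9% of the pooled library. These shares leave out the 216 and 253 unnamed cells, whose clusters scored best as T cells, and a sort by CD45 can set them. The cluster of 253 cells was led by GNLY and KRT86 and stayed unnamed because KLRC1, a marker of NK cells, was among its leading genes.

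Among the reclustered T and NK cells, regulatory T-like cells were 639 of 2036 (31.4%) in the single-donor library and 1233 of 7148 (17.2%) in the pooled library. Of the 639, 236 came from a cluster led by S100A8 and S100A9, genes of neutrophils and monocytes, with a median of 1152.5 UMIs. In the clustering of all cells, the cluster of 216 cells led by the same genes had stayed unnamed because of them. Exhausted-like CD8 T cells were 89 of 777 CD8 T-like cells (11.5%, 9.30 to 13.9) in the single-donor library and 350 of 4886 (7.16%, 6.46 to 7.92) in the pooled library. Leading genes of the exhausted-like cluster included KRT86, GZMB, GZMH, KLRC2, TMIGD2 and GNLY in the single-donor library. In the pooled library they included SMIM3, SOX4, HTRA1, APOD, CXCL13 and ZNF683, and no leading gene was shared. KRT86, TMIGD2 and GNLY also led the NK-like cluster of the reclustered pooled cells. APOD, CXCL13 and LRRN3, leading genes of the pooled exhausted-like cluster, also led a single-donor cluster that was kept out of the CD8 class (below). That single-donor cluster shared CXCL13, IL21, NMB and G0S2 with a CD4 cluster of the pooled library. Whether both exhausted-like clusters hold like cells was not tested, so values given for both libraries may not describe 1 state. The other CD8 T-like cells of the pooled library included a cluster of 15 cells led by S100A8, CXCL8 and other genes that myeloid cells express, CCL3 among them. Across the alternative settings, which changed cell filters, clustering or the definition one at a time, the exhausted-like shares ran from 10.1% to 62.8% in the single-donor library and from 6.51% to 75.8% in the pooled library. A rule set after the values had been seen kept clusters out of the CD8 class where the median CD4 antibody count was at or above the median CD8 antibody count. It left out a cluster led by CXCL13 and IL21 (8.79% of reclustered cells, 7.60 to 10.1) and a cluster led by EGR1 and TNF (5.89%, 4.91 to 7.01), both in the single-donor library. Both scored best as CD8 by RNA. Median CD8 and CD4 antibody counts were 5 and 232 in the first but 12.5 and 14, near parity, in the second, which had 3821 CPM of CD69 RNA. A pooled cluster of 1165 cells with TNF and EGR1 among its leading genes stayed, at 29 and 4. No alternative setting that used clusters dropped this rule.

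The first comparison asked which effector genes differed between exhausted-like and other CD8 T cells. GZMB, the gene of the granule protease granzyme B, was 6.07 times higher in exhausted-like cells of the single-donor library (5.54 to 6.65) and 3.35 times higher in the pooled library (3.23 to 3.48). GNLY, which encodes the pore-forming peptide granulysin, was 3.33 times (3.14 to 3.54) and 5.45 times (5.31 to 5.60) higher. The opposite held for GZMK, a granzyme of memory-like CD8 T cells, which was 6.66 times lower (5.33 to 8.44) in the single-donor library and 19.9 times lower (14.0 to 29.4) in the pooled library. ITGAE, the integrin chain CD103 of tissue-resident T cells, was 4.05 times (2.86 to 5.74) and 1.89 times (1.57 to 2.25) higher. KLF2, a transcription factor of circulating T cells, was 15.2 times lower (7.32 to 38.1) and 5.63 times lower (3.91 to 8.43).

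Of the 11 cytotoxic genes, 3 were at least 1.5 times higher and 2 at least 1.5 times lower in both libraries. FGFBP2 was 1 of the 2, with 0 UMIs against 20 in the single-donor library (at least 1.60-fold lower) and 1 UMI against 361 in the pooled library (ratio 0.0416, 0.00105 to 0.233). The median log2 ratio of the list was 0.59 (−0.26 to 0.74) in the single-donor library, at percentile 98.2 among 10000 random lists matched on expression, and −0.12 (−0.19 to 0.00) in the pooled library, at percentile 31.6. Across the alternative settings the median ran from −0.30 to 0.77 in the pooled library and was above 0 in 8 of 14, and from −0.21 to 0.72 in the single-donor library, above 0 in 12 of 14.

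Of the 8 cytokine and chemokine genes counted, 1 was at least 1.5 times higher in both libraries and 0 were lower. That gene was CCL3, which encodes a chemokine that attracts myeloid and T cells, with ratios of 3.76 (2.65 to 5.34) and 2.42 (2.05 to 2.85). Without the CD8 clusters of stress or cycling genes or low UMI counts, the 15 cells led by S100A8 among them, the pooled ratio was 2.76. The list medians were 0.09 at percentile 51.2 and −0.06 at percentile 30.1, and the pooled library's median was below 0 in all 14 alternative settings, down to −0.93.

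**Figure D1:**
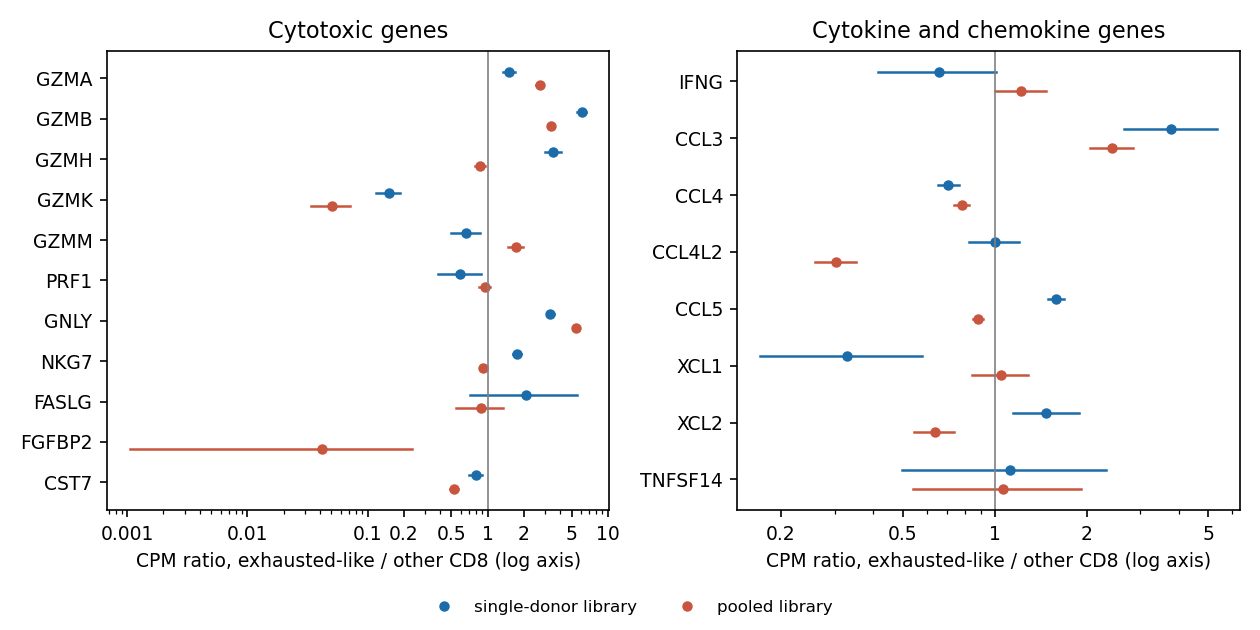
Ratios of CPM in exhausted-like over other CD8 T cells for the cytotoxic genes (left) and the cytokine and chemokine genes (right), on log axes. Points are 1 library each and lines are exact 95% counting intervals; GZMB and GNLY lie above 1 and GZMK below 1 in both libraries, and FGFBP2 had 0 UMIs in exhausted-like cells of the single-donor library, so it has no point there.

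Naive and memory genes were lower in exhausted-like cells. Of 12 members 8 were at least 1.5 times lower in both libraries, with list medians of −2.18 and −1.07, both below every random list (percentile 0). TCF7, a transcription factor of memory and progenitor T cells, had 2 UMIs in exhausted-like cells of the single-donor library (ratio 0.107, 0.0127 to 0.399) and 1 UMI in the pooled library (0.111, 0.00280 to 0.631). Of the 16 early response genes of T cell receptor signalling, 8 were lower in both libraries, with medians of −1.77 and −0.62 and percentile 0 in both. EGR1 was 7.15 times lower (3.00 to 22.3) and 4.71 times lower (2.00 to 14.6). MYC had 1 UMI in the single-donor library (ratio 0.0947, 0.00235 to 0.556) and was 4.56 times lower (1.76 to 16.8) in the pooled library. Heat shock genes were lower in 4 of 8 cases in both libraries, with medians of −0.84 (percentile 3.06) and −0.82 (percentile 0.01). HSPH1 was 5.39 times lower (3.22 to 9.74) and 3.31 times lower (2.79 to 3.95), and HSPD1 was 1.79 times (1.27 to 2.58) and 2.67 times lower (2.29 to 3.13). A heat shock cluster of 937 cells sat among the other CD8 T cells of the pooled library, and a cluster of 399 cells with a median of 997 UMIs and led by HSPA5 sat among those of the single-donor library. In the single-donor library the naive and memory, early response and heat shock medians turned above 0 at the lower clustering resolution (0.75, 1.27 and 1.23) and where clusters were added to the exhausted-like class one at a time (1.86, 1.23 and 1.06). Without the clusters of stress or cycling genes or low UMI counts, a setting added after the data had been seen, they were −1.87, −0.74 and −0.26, and HSPD1 turned to 0.35. The pooled heat shock median rose to −0.16 under another setting.

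Of 8 tissue residency genes 3 were at least 1.5 times higher in both libraries, with medians of 0.43 (−0.11 to 0.73, percentile 93.0) and 0.82 (0.71 to 1.21, percentile 99.99), the latter down to 0.10 under another setting. ZNF683, which encodes the residency factor Hobit, was 2.44 times (1.41 to 4.14) and 8.18 times (6.43 to 10.4) higher. Of 9 glycolysis genes 1 was higher in both libraries, PKM, the pyruvate kinase of the last step of glycolysis, at 2.78 (1.77 to 4.32) and 1.59 (1.41 to 1.79). The glycolysis medians were 0.57 (percentile 96.1) and 0.29 (percentile 97.1), and the pooled one turned below 0 in 2 of 14 settings (−0.12 and −0.067). Oxidative phosphorylation genes had medians of 0.79 (percentile 99.8) and 0.14 (percentile 87.8), with 0 of 13 members 1.5 times apart in both libraries. They turned below 0 in 3 of 14 settings in the single-donor library (−0.42, −0.87 and −0.59) and in 6 of 14 in the pooled library, TMM factors among them (−0.041). Of 11 interferon response genes 1 was lower in both libraries, IFIT2, with 2 UMIs in the single-donor library (ratio 0.167, 0.0197 to 0.635) and 4.24 times lower (2.36 to 8.53) in the pooled library. The interferon medians were −0.35 (percentile 32.5) and 0.06 (percentile 55.5), and the single-donor one turned above 0 in 5 of 14 settings, up to 1.74. The 3 cycling genes counted had medians of 0.70 (percentile 92.1) and −0.83 (percentile 0.140), and a cluster of 208 cycling cells sat among the other CD8 T cells of the pooled library. The pooled cycling median turned above 0 in 4 of 14 settings, up to 2.05, and was 0.43 without the clusters of stress or cycling genes or low UMI counts.

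CD69 RNA was lower in exhausted-like cells, 6.97 times (5.39 to 9.18) in the single-donor library and 1.2 times (1.08 to 1.34) in the pooled library. The other CD8 T cells of the single-donor library were a cluster of 399 cells with a median of 997 UMIs and 3162 CPM of CD69 and a cluster of 289 cells with 408 CPM, against 224 CPM in exhausted-like cells. Without the first of these, CD69 was 1.82 times lower. CD8A, 1 of the CD8 chains, had ratios of 0.960 (0.759 to 1.2) and 0.880 (0.806 to 0.959), and CD8B, the other chain, had 1.44 (1.22 to 1.69) and 1.23 (1.11 to 1.36). The pooled exhausted-like cluster also held more CD4, the coreceptor of helper T cells, at 40.8 against 9.81 CPM of RNA and an antibody ratio of 1.54 (1.5 to 1.57), and more CD25, a receptor chain of regulatory and activated T cells, with an antibody ratio of 1.51 (1.46 to 1.57). In the single-donor library the CD4 and CD25 antibody ratios were 0.291 (0.282 to 0.300) and 1.47 (1.39 to 1.55). In the pooled library the single exhausted-like cluster met 6 of 10 exhaustion markers, yet other clusters were close to it or above it in some markers: PDCD1 was at 228, 208 and 213 CPM and HAVCR2 at 203, 187 and 177 CPM in 3 of the other CD8 clusters (1534, 937 and 450 cells), against 337 and 173 CPM in the exhausted-like cluster. In the same 3 clusters TNFRSF9 was at 569, 470 and 277 CPM, against 259 CPM in the exhausted-like cluster. TOX was at 110, 130 and 88.3 CPM, against 113 CPM. In the single-donor library the other CD8 cluster of 399 cells was close to the exhausted-like cluster in some markers, though above it in none. TOX was at 66.2 against 67.2 CPM, LAG3 at 190 against 213 and CTLA4 at 199 against 224, while CXCL13 was at 115 against 1722. PDCD1 was at 34.2 against 48.6 CPM, in an exhausted-like group of 267665 UMIs, and the rule set no minimum count per marker. Across all settings tried, GZMB and ITGAE kept their direction in both libraries, but their log2 ratios went down to 0.51 and 1.16 in the single-donor library and to 0.11 and 0.077 in the pooled library. The other genes named for this comparison turned sign in at least 1 library under some setting of how cells were filtered, clustered or called exhausted-like. Exceptions were CD4, CD25, PDCD1, HAVCR2, TNFRSF9, TOX, LAG3, CTLA4 and CXCL13, which were not computed under other settings.

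The second comparison asked whether exhausted-like CD8 T cells with a CD69 transcript carried more effector RNA than those without. CCL4, a chemokine secreted by activated T cells, was 3.37 times higher (2.73 to 4.17) in cells with a CD69 UMI of the single-donor library and 2.02 times higher (1.72 to 2.38) in those of the pooled library, and its log2 ratio went down to 0.068 and 0.26 under other settings. XCL2, a chemokine for cross-presenting dendritic cells, had ratios of 1.83 (0.811 to 3.89) and 2.27 (1.47 to 3.54), which turned below 1 in 4 and 2 of 17 settings. FOS, an immediate early transcription factor, was 9.33 times (3.37 to 29.6) and 6.59 times (4.15 to 10.8) higher, and cytotoxic genes showed no common direction. The log2 ratio of FOS went down to 0.78 and 1.01 under other settings.

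All cells were thinned to 1500 UMIs, which left out 14 exhausted-like cells of the single-donor library and 133 of the pooled library. A CD69 UMI was found in 15 of 75 cells of the single-donor library (20%, 11.6 to 30.8; 30.3% before thinning) and 77 of 217 of the pooled library (35.5%, 29.1 to 42.2; 41.7% before thinning). Plasma-like cells of the pooled library, taken as a class that should lack CD69, had a UMI in 7 of 149 cells (4.70%, 1.91 to 9.44). The mixed plasma-like cluster of the single-donor library had one in 5 of 39 cells (12.8%, 4.30 to 27.4), and since myeloid cells can express CD69 it was not taken as background. Median depths before thinning were 2555 UMIs in exhausted-like and 6279 in plasma-like cells of the single-donor library, and 1645.5 and 11983 in the pooled library. Thinning thus kept a smaller part of the UMIs of plasma-like than of exhausted-like cells, and 4.70% may understate the background in the pooled library. The single-donor share has no background value beside it.

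The 5 genes counted from the cytokine and chemokine list were all chemokines (CCL3, CCL4, CCL4L2, CCL5 and XCL2). The list therefore says nothing here on IFNG, TNF or other cytokines. Of these 5 genes, 2 were at least 1.5 times higher in both libraries. The median log2 ratio was 0.87 (0.21 to 1.77) in the single-donor library and 1.01 (0.48 to 1.18) in the pooled library, above every random list in both (percentile 100). With 5 genes each median was the value of 1 gene, XCL2 in the single-donor library and CCL4 in the pooled library. The list median was above 0 in all 17 alternative settings in each library, from 0.19 to 1.82 and from 0.26 to 1.05. The 7 cytotoxic genes had medians of −0.26 (percentile 0.610) and 0.15 (percentile 99.7), and 0 of them were 1.5 times apart in both libraries. Random lists keep the split fixed, so these percentiles do not cover which cells fall in each group. For the pooled cytokine and chemokine list the central range of random lists was −0.28 to 0.15. Splits of the same cells by control genes (below) gave −0.71 to 0.52, and 1.01 lay above both. No such range is given for other lists or the single-donor library, so their percentiles do not show a shift beyond variation between cells. The cytotoxic median ran from −1.02 to 0.40 and from −0.36 to 0.24 across the settings. The 7 early response genes had medians of 0.68 (percentile 99.7) and 0.53 (percentile 100). JUN, the partner of FOS, had ratios of 1.93 (0.912 to 3.86) and 1.60 (1.30 to 1.98), and the first turned below 1 in 1 of 17 settings. The lowest log2 values were 0.21 for JUN in the pooled library and 0.15 and 0.25 for the early response medians. Outside the lists, KLF6, a stress-responsive transcription factor, was 2.69 times (1.68 to 4.27) and 1.89 times (1.46 to 2.45) higher, with log2 ratios down to 0.73 and 0.41 under other settings. CD8A had ratios of 1.00 (0.398 to 2.22) and 1.06 (0.821 to 1.35), and CD8B 0.831 (0.453 to 1.44) and 1.09 (0.818 to 1.45).

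The remaining lists moved less or in opposite ways in the 2 libraries. The 3 heat shock genes had medians of −1.40 (percentile 0.120) and 0.65 (percentile 99.4), the 2 residency genes −0.05 and 0.00, the 3 interferon genes −0.33 and −0.37, the 5 glycolysis genes 0.18 and −0.25, the 12 oxidative phosphorylation genes −0.40 and −0.14, and the 1 cycling gene −0.49 and 0.06. No naive or memory gene reached 20 UMIs in both libraries.

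**Figure D2:**
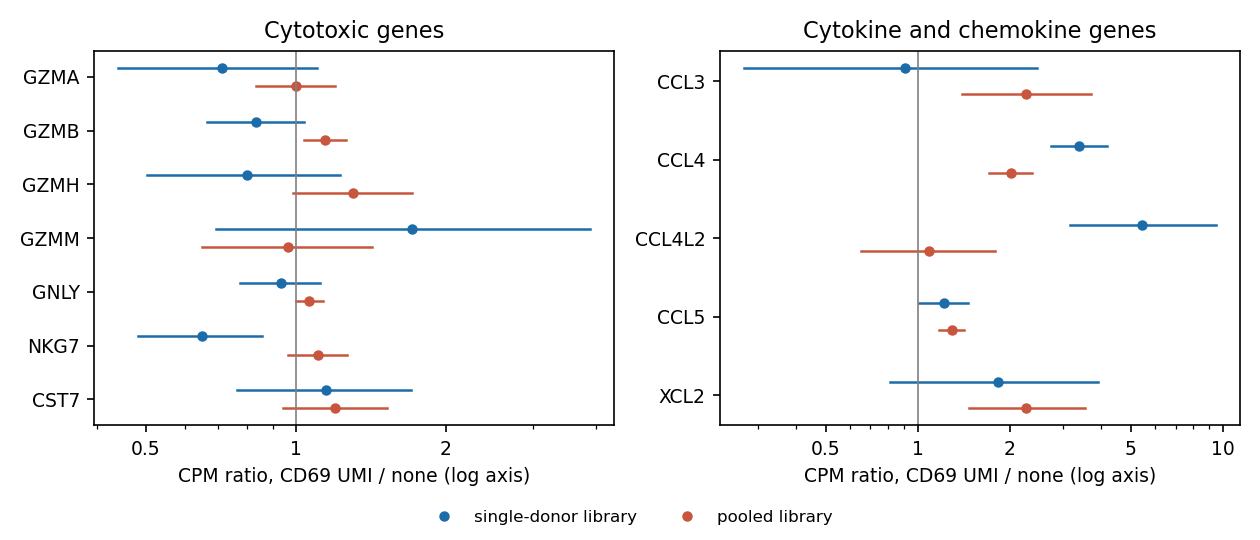
Ratios of CPM in exhausted-like CD8 T cells with a CD69 UMI over those with none, each cell thinned to 1500 UMIs, for the cytotoxic genes (left) and the cytokine and chemokine genes (right), on log axes. Points are 1 library each and lines are exact 95% counting intervals; CCL4 lies at 3.37 and 2.02, above 1 in both libraries.

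Splitting the same cells at the median CD69 antibody count (422 in the single-donor library, 75 in the pooled library) gave 4 quadrants. Among antibody-high cells, 7 with and 30 without a CD69 UMI in the single-donor library and 37 and 71 in the pooled library, the cytokine medians were 0.95 and 0.65 and the cytotoxic medians −0.29 and 0.21. Among antibody-low cells, 8 and 30 in the single-donor library and 40 and 69 in the pooled library, the cytokine medians were 1.59 and 0.17 and the cytotoxic medians −0.47 and 0.08. Antibody-high against antibody-low cells, with RNA ignored, gave cytokine medians of −0.96 and 0.01 and cytotoxic medians of −0.11 and −0.14. The medians rested on 2 to 7 genes, only chemokines in the cytokine list, and on few cells. Quadrant medians turned sign under some settings in both libraries. The median CD69 antibody count was 422 with and 417.5 without a CD69 UMI in the single-donor library, and 73 and 76.5 in the pooled library.

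The third comparison set surface proteins against their RNA. In exhausted-like against other CD8 T cells, 12 antibodies were at least 1.5 times higher and 11 at least 1.5 times lower as shares of all antibody counts in both libraries, and 0 of the 7 isotype controls were among them. CD39, the ectonucleotidase encoded by ENTPD1, was 9.37 times and 1.81 times higher, and the integrin CD103 6.36 times and 1.96 times. PD-1, the inhibitory receptor targeted by checkpoint therapy, was 2.28 times and 1.56 times higher, and CD49a, a collagen-binding integrin, 2.03 times and 3.03 times. The single-donor value of CD49a was next to the highest isotype control ratio of that library, 2.02. The naive or memory proteins CD45RA, CD62L, CD127 and CD28 were among the 11 lower ones. ENTPD1 and PDCD1, the genes of CD39 and PD-1, were among the markers that named the exhausted-like clusters, so the direction of these 2 proteins is not independent of the naming.

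The other higher antibodies were integrin beta 7, CD49b, CD86, CD146, CD161, GPR56, CD101 and CD94, and the other lower ones were CD5, KLRG1, CD49f, CD48, CD52, CD47 and CD45. The numbers of antibodies higher and lower ran from 0 to 12 and from 2 to 13 across the alternative settings. In at least 1 library and setting the direction turned for CD49a, CD86, CD94, CD101, CD146, CD161, CD45, CD47, CD48, CD49f, CD52 and CD127. In the pooled library CD161 turned in 6 of 14 settings and CD49a in 2 (−0.22 and −0.056). The lowest log2 ratios in the single-donor and pooled libraries were 1.45 and 0.44 for CD39, 0.95 and 0.15 for CD103 and 0.32 and 0.25 for PD-1. Exhausted-like cells carried more antibody counts in total, 9524 against 5644 per cell in the single-donor library and 2198 against 1827 in the pooled library. With a higher total, an antibody can be lower as a share without fewer counts per cell. This applies to CD45 in the single-donor library, at a log2 ratio of shares of −0.78, so its lower share does not show less protein there. Isotype ratios ran from 1.09 to 2.02 in the single-donor library and from 0.845 to 0.975 in the pooled library. In the single-donor library the higher antibodies CD94 and CD101, at log2 ratios of 0.59 and 0.97, lay within the isotype range. CD49a, at a log2 ratio of 1.02, lay at its upper end.

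The CD69 antibody was 1.5 times higher as a share of antibody counts in exhausted-like cells of the single-donor library (1.48 to 1.52), where CD69 RNA was 6.97 times lower. Without the other CD8 cluster of low UMI counts, CD69 RNA was 1.82 times lower. In 2 of 14 settings CD69 RNA was higher there, up to a log2 ratio of 2.36, and the antibody was higher in all 14. In the pooled library the ratio of the CD69 antibody was 0.584 (0.577 to 0.590), a value that turned above 1 in 6 of 14 settings, and CD69 RNA was 1.2 times lower. The exhausted-like cluster of the single-donor library had 224 CPM of CD69 RNA and 495 antibody counts per cell, against 3162 CPM and 178 counts in the CD8 cluster with the most CD69 RNA. Across 118 antibodies matched to a gene, the Spearman correlation of antibody count and RNA was 0.649 and 0.660 in exhausted-like cells, 0.703 and 0.672 in other CD8 T cells, 0.690 and 0.686 in regulatory T-like cells, and 0.671 and 0.473 in B-like cells. The ratios of exhausted-like to other CD8 T cells correlated at 0.681 over 74 antibodies in the single-donor library and 0.574 over 85 in the pooled library. These correlations are across proteins of 1 library, which are not independent replicates.

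**Figure D3:**
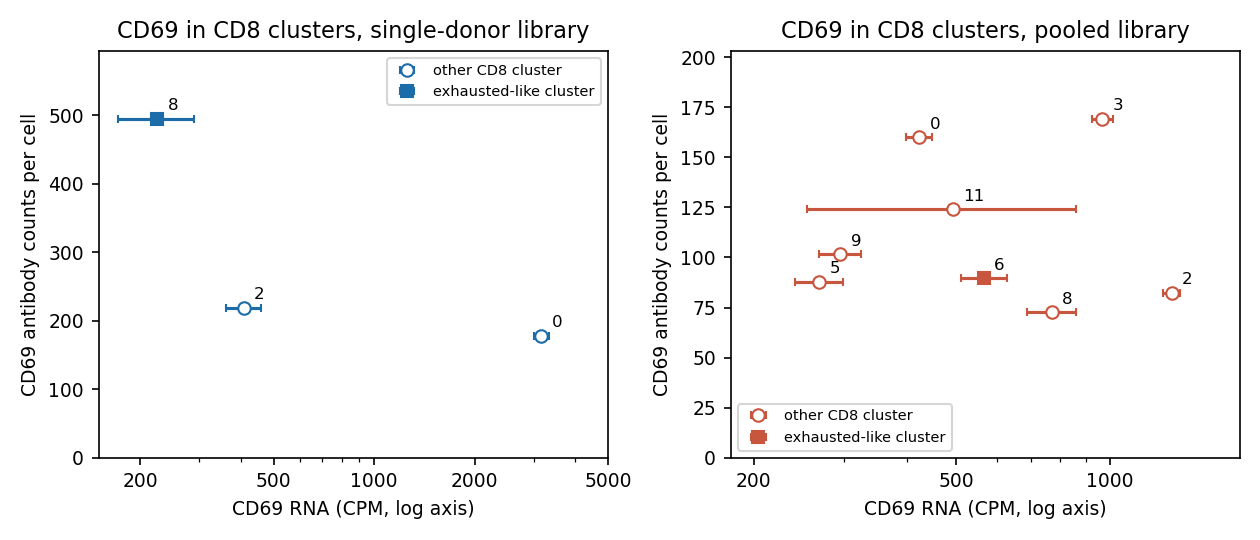
CD69 RNA in CPM (horizontal, log axis) against CD69 antibody counts per cell (vertical) for each CD8 T-like cluster of the single-donor library (left) and the pooled library (right), labelled by cluster number, with filled squares for the exhausted-like clusters and exact 95% counting intervals on the RNA axis. The exhausted-like cluster lies at 224 CPM and 495 counts in the single-donor library and at 566 CPM and 89.6 counts in the pooled library.

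The fourth comparison set exhausted-like CD8 T cells of the single-donor library against those of the pooled library, which compares 2 libraries and not 2 conditions. MT-CO3, a mitochondrially encoded subunit of cytochrome oxidase, was 12.6 times higher in the single-donor library (10.7 to 14.9) and RPS29, a ribosomal protein gene, 8.62 times (7.41 to 10.1). Over all filtered cells of each library, mitochondrial genes took a median of 3.97% and 0.624% of the UMIs. HSPA1A, the inducible chaperone HSP70, was 28.2 times lower in it (19.7 to 41.8), and DUSP1, an immediate early phosphatase, 7.99 times lower (5.57 to 11.9). GZMK was 6.15 times higher (4.01 to 9.63) and PRF1, which encodes perforin, 5.86 times lower (3.99 to 8.94).

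Of 9 heat shock genes 8 were at least 1.5 times lower in the single-donor library, with a median of −2.45 (percentile 0), and HSPA6, at 0 UMIs against 130, was at least 18.2-fold lower. Of 14 early response genes 10 were lower and 2 higher (FOSB 2.10 times, 1.13 to 3.87, and NR4A3 1.53 times, 0.798 to 2.87), with a median of −1.38 (percentile 0), and NR4A1, an orphan receptor induced by T cell receptor signals, was 6.09 times lower (3.40 to 12). Of 9 glycolysis genes 5 were lower (median −1.17, percentile 0.0900), PGK1 by 4.98 times (3.71 to 6.81). Of 8 interferon genes 3 were higher and 1 lower (median 0.43, percentile 98.4), and IFI6, an interferon-induced gene, was 4.07 times higher (3.14 to 5.29) and ISG15 2.26 times higher (1.92 to 2.67). The cytotoxic median was −0.23 (percentile 9.79; 2 of 10 higher, 2 lower), the cytokine median 0.16 (percentile 85.1; 2 of 8 higher, 2 lower), the naive and memory median −0.94 (percentile 11.8), the residency median −0.94 (percentile 1.05), with CXCR6, a residency-linked chemokine receptor, 6.23 times lower (4.15 to 9.75), the cycling median −0.98 (percentile 6.88) and the oxidative phosphorylation median 0.08 (percentile 65.3). CD69 was 2.53 times lower (1.92 to 3.38), CD8A 2.45 times lower (1.97 to 3.08), and CD8B had a ratio of 1.16 (0.974 to 1.37). PDCD1, which encodes PD-1, was 6.94 times lower (3.97 to 13.3), and TSC22D3, a glucocorticoid-induced gene, 6.01 times lower (5.26 to 6.90).

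The ratio compares 1 cluster per library, with different leading genes, and PDCD1 is 1 of the markers by which those clusters were named. Under other cell filters, clustering or exhaustion rules GZMK and the residency median turned sign in 7 of 13 settings each (−1.79 and −2.54, and 0.28 and 0.0098, under cell filters alone), the naive and memory median in 6, the cycling median in 5, CD69 and the early response median in 3 and ISG15 in 1 (−0.84 at the finer clustering), as did FOSB (−0.28) and NR4A3 (−0.18). Values that kept their direction still shrank under some setting: RPS29 to 0.39, HSPA1A to −2.28, DUSP1 to −1.57, NR4A1 to −0.43, PRF1 to −1.20, PGK1 to −1.11, CXCR6 to −0.93, PDCD1 to −1.80, TSC22D3 to −1.55, the heat shock median to −0.45 and the glycolysis median to −0.41. Of the medians nearer 0, the cytokine one changed sign in 8 settings, the oxidative phosphorylation one in 4 and the cytotoxic one in 1, and the ratio of CD8B crossed 1 in 5.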

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

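Tests chosen only after results had been seen were the doublet removal at the expected rate, both forms in which clusters were added one at a time, the antibody gate, the removal of doubted CD8 clusters and the CD69 share of antibody counts. The other settings were planned. Of the 231 alternative values of results that answer a comparison, 139 stayed within their interval or within 1.5 times a count, 78 moved and 14 turned sign from an interval that excluded 0. Whatever the interval, 35 of the 165 log2 values among them lay on the other side of 0 from the reported value. Of 2885 alternative values for other lists, single genes and antibodies, among them genes that the text could name but leaves out, 1657 stayed, 1019 moved and 209 turned sign from an interval that excluded 0, and 354 lay on the other side of 0 whatever the interval. Over every gene that the naming rule picked, 368 of 6158 turned sign in that sense, 1715 moved and 4075 stayed, and 1188 of 6092 log2 values lay on the other side of 0; the genes followed here are fewer, a choice made after a first table of these values had been seen. Cell filters, clustering and the exhausted-like definition each moved the pooled exhausted-like share, which ran from 6.51% to 75.8%, and the pooled cytotoxic median and CD69 antibody ratio took both signs. The cytokine and chemokine median of the CD69 split, which at the reported setting rested on chemokines alone, stayed above 0 in all 17 settings in each library. Depth limits the CD69 split of the single-donor library, with 15 cells against 60. No paired analysis was possible because each matrix is 1 sample and the labels give no shared replicate numbers. The CD69 share of antibody counts and the setting with no minimum count required no value here. For all values below the cause was not tested. Values that turned sign left an interval that excluded 0, and values that crossed 0 left one that included it. Values are log2 ratios or list medians unless a share or number is named. The exhaustion contrast is exhausted-like against other CD8 T cells, the CD69 split is cells with against without a CD69 UMI, and the antibody splits are those of the CD69 antibody.

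With up to 25% mitochondrial UMIs, the number of antibodies at least 1.5 times higher in each library was 6. The T-like share was 88.3% in the single-donor library. The exhausted-like share was 35.9% in the pooled library. The cytotoxic list 0.50 crossed 0 in the exhaustion contrast of the pooled library. The cytokine list -0.47 moved in the exhaustion contrast of the pooled library. The oxidative phosphorylation list -0.066, CD8A 0.65, GZMK 0.055, IFIT2 0.41, PKM -0.19, the CD69 antibody 0.37 and the CD161 antibody -0.16 turned sign in the exhaustion contrast of the pooled library. The cytotoxic list 0.025 crossed 0 in the CD69 split of the single-donor library. The cytotoxic list 0.0072 and the cytokine list 0.34 moved in the CD69 split of the pooled library. The residency list 0.28, the cycling list 0.51, CXCL13 0.43, GNLY 1.18, GZMK -1.79, NELL2 0.32 and TYMS 0.0085 turned sign between the libraries. The CD69 antibody 0.54 moved in the exhaustion contrast of the single-donor library.

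With at least 500 genes and at most 10% mitochondrial UMIs per cell, the number of antibodies at least 1.5 times higher in each library was 0. The T-like share was 86.2% in the single-donor library and 68.6% in the pooled library. The exhausted-like share was 28.2% in the pooled library. The cytotoxic list 0.43 crossed 0 in the exhaustion contrast of the pooled library. The cytokine list -0.57 moved in the exhaustion contrast of the pooled library. The glycolysis list -0.12, the oxidative phosphorylation list -0.13, CCL3 -0.26, CD8A 0.73, GNLY -0.76, GZMK 0.43 and IFIT2 0.71 turned sign in the exhaustion contrast of the pooled library. PKM -0.54, ZNF683 -3.10, the CD69 antibody 0.59, the CD86 antibody -0.23, the CD48 antibody 0.13, the CD52 antibody 0.031 and the CD146 antibody -0.74 turned sign in the exhaustion contrast of the pooled library. The CD161 antibody -0.63, the CD45 antibody 0.12, the CD49a antibody -0.22, the CD94 antibody -0.68 and the CD101 antibody -0.15 turned sign in the exhaustion contrast of the pooled library. The cytotoxic list 0.29 crossed 0 in the CD69 split of the single-donor library. The cytotoxic list -0.055 and XCL2 -0.26 turned sign in the CD69 split of the pooled library. The cytokine list 0.26 moved in the CD69 split of the pooled library. The cytotoxic list -0.40 moved between the libraries. The naive-memory list 1.04, the residency list 0.0098, the cycling list 1.63, CCL4L2 -0.077, CXCL13 1.96, GNLY 1.99 and GZMK -2.54 turned sign between the libraries. IFNG 0.078, NELL2 1.85, SMIM3 2.91, TUBB 0.62 and TYMS 1.52 turned sign between the libraries. The cytotoxic list -0.020 turned sign in the antibody-high split of the pooled library. The cytotoxic list 0.50 turned sign in the antibody-low split of the single-donor library. The CD69 antibody 0.45 moved in the exhaustion contrast of the single-donor library.

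With doublets kept, the cytokine list -0.10 turned sign in the antibody-high split of the single-donor library. The cytotoxic list 0.043 turned sign in the antibody-low split of the single-donor library. The CD69 antibody 0.67 moved in the exhaustion contrast of the single-donor library.

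At resolution 0.6, the number of antibodies at least 1.5 times higher in each library was 6. The number of antibodies at least 1.5 times lower in each library was 5. The exhausted-like share was 52.6% in the single-donor library and 49.1% in the pooled library. The T-like share was 67.6% in the pooled library. The naive-memory list 0.75, the early response list 1.27, the interferon list 1.74, the oxidative phosphorylation list -0.42, the heat shock list 1.23, CD69 2.18 and CD8B -0.21 turned sign in the exhaustion contrast of the single-donor library. EGR1 1.46, HSPD1 1.47, HSPH1 1.95, IFIT2 1.74, MYC 0.36 and TCF7 0.69 turned sign in the exhaustion contrast of the single-donor library. The cytotoxic list 0.77 crossed 0 in the exhaustion contrast of the pooled library. The cytokine list -0.93 moved in the exhaustion contrast of the pooled library. The oxidative phosphorylation list -0.027, CD8A 0.75, FGFBP2 0.33, GZMK 0.27, IFIT2 0.12, PKM -0.17 and the CD69 antibody 0.28 turned sign in the exhaustion contrast of the pooled library. The CD161 antibody -0.23 turned sign in the exhaustion contrast of the pooled library. The heat shock list 0.48 turned sign in the CD69 split of the single-donor library. The cytotoxic list -0.041 and the glycolysis list 0.057 turned sign in the CD69 split of the pooled library. The cytotoxic list -0.90 moved between the libraries. The naive-memory list 2.45, the residency list 0.16, the early response list 0.87, the cycling list 0.26, CCL4L2 -0.75, CD69 1.91 and CXCL13 1.03 turned sign between the libraries. GZMH -0.90, GZMK -0.16, IFNG 1.32, NELL2 0.99 and XCL1 0.18 turned sign between the libraries. The cytokine list 0.029 turned sign in the antibody split of the single-donor library. The CD69 antibody 0.52 moved in the exhaustion contrast of the single-donor library.

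At resolution 1.5, the number of antibodies at least 1.5 times higher in each library was 4. The T-like share was 81.8% in the single-donor library. The exhausted-like share was 22.5% in the pooled library. The interferon list 1.01, the oxidative phosphorylation list -0.87, CD8B -1.13, HSPD1 0.44 and TCF7 0.10 turned sign in the exhaustion contrast of the single-donor library. The cytotoxic list 0.51 crossed 0 in the exhaustion contrast of the pooled library. The cytokine list -0.59 moved in the exhaustion contrast of the pooled library. The glycolysis list -0.067, the oxidative phosphorylation list -0.057, CD8A 0.54, PKM -0.067 and the CD69 antibody 0.074 turned sign in the exhaustion contrast of the pooled library. The cytotoxic list -1.02 moved in the CD69 split of the single-donor library. The heat shock list 0.058 turned sign in the CD69 split of the single-donor library. The cytotoxic list -0.043 turned sign in the CD69 split of the pooled library. The cytotoxic list -1.07 moved between the libraries. The naive-memory list 1.48, the residency list 0.64, the early response list 0.59, the cycling list 0.21, ATP5ME -0.84, CCL4L2 -0.73 and CD69 1.36 turned sign between the libraries. CXCL13 1.43, GZMH -0.94, GZMK -2.15, IFNG 2.37, ISG15 -0.84, NELL2 1.07 and RGS2 0.16 turned sign between the libraries. RPSA -0.014, TYMS 0.045 and XCL1 1.59 turned sign between the libraries. The cytotoxic list -0.042 turned sign in the antibody-high split of the pooled library. The CD69 antibody 0.37 moved in the exhaustion contrast of the single-donor library.

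With 3000 variable genes, the exhausted-like share was 18.3% in the pooled library. The cytotoxic list 0.41 crossed 0 in the exhaustion contrast of the pooled library. The cytokine list -0.82 and the CD69 antibody -0.18 moved in the exhaustion contrast of the pooled library. The oxidative phosphorylation list -0.012, CD8A 0.51 and FGFBP2 0.25 turned sign in the exhaustion contrast of the pooled library. The cytotoxic list 0.12 crossed 0 in the CD69 split of the single-donor library. The cytotoxic list 0.0027 moved in the CD69 split of the pooled library. The naive-memory list 0.49, the cycling list 0.88, GNLY 0.30, GZMK -1.33, IFNG 0.44 and TUBB 0.33 turned sign between the libraries. The cytokine list -0.89 turned sign in the antibody-high split of the single-donor library. The cytokine list 0.016 turned sign in the antibody split of the single-donor library.

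Under TMM factors, the cytotoxic list -0.30 moved in the exhaustion contrast of the pooled library. The oxidative phosphorylation list -0.041 turned sign in the exhaustion contrast of the pooled library. The cytotoxic list -0.74 moved in the CD69 split of the single-donor library.

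Under the cell gate, the number of antibodies at least 1.5 times higher in each library was 3. The number of antibodies at least 1.5 times lower in each library was 3. The exhausted-like share was 20.1% in the single-donor library and 58.9% in the pooled library. The interferon list 0.81, the heat shock list 0.13, CD8B -0.070 and HSPD1 0.50 turned sign in the exhaustion contrast of the single-donor library. The cytotoxic list 0.24 crossed 0 in the exhaustion contrast of the pooled library. The cytokine list -0.45 and the CD69 antibody -0.070 moved in the exhaustion contrast of the pooled library. The cycling list 1.82, CD8B -0.15, FGFBP2 0.27, ZNF683 -1.03, the CD146 antibody -0.94, the CD161 antibody -0.035 and the CD49a antibody -0.056 turned sign in the exhaustion contrast of the pooled library. The CD101 antibody -0.11 turned sign in the exhaustion contrast of the pooled library. The heat shock list 0.44 turned sign in the CD69 split of the single-donor library. The cytotoxic list -0.080 and XCL2 -0.26 turned sign in the CD69 split of the pooled library. The naive-memory list 0.22, the residency list 1.56, CCL4L2 -0.48, CXCL13 0.88, GNLY 1.29, GZMK -0.69 and IFNG 0.32 turned sign between the libraries. NELL2 1.92 and SMIM3 1.32 turned sign between the libraries. The cytokine list 0.39 turned sign in the antibody split of the single-donor library. The CD69 antibody 0.45 moved in the exhaustion contrast of the single-donor library.

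After thinning to 1000 UMIs, the cytokine list 1.82 moved in the CD69 split of the single-donor library. The cytokine list 0.044 turned sign in the antibody split of the single-donor library.

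After thinning to 2500 UMIs, the cytotoxic list 0.40 crossed 0 in the CD69 split of the single-donor library. The cytotoxic list -0.36 and the heat shock list -0.60 turned sign in the CD69 split of the pooled library. The cytotoxic list -0.51 turned sign in the antibody-high split of the pooled library.

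Without thinning, the cytotoxic list -0.054 and the interferon list 0.014 turned sign in the CD69 split of the pooled library. The cytotoxic list 0.068 turned sign in the antibody-low split of the single-donor library.

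For 2 or more CD69 UMIs against none, the cytokine list -0.046 turned sign in the antibody-low split of the single-donor library.

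With doublets removed at the expected rate, the T-like share was 67.3% in the pooled library. The cytokine list 0.19 moved in the CD69 split of the single-donor library. The cytokine list -0.30 turned sign in the antibody-low split of the single-donor library. The CD69 antibody 0.56 moved in the exhaustion contrast of the single-donor library. The CD69 antibody -0.81 moved in the exhaustion contrast of the pooled library.

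With clusters added one at a time, the number of antibodies at least 1.5 times higher in each library was 7. The number of antibodies at least 1.5 times lower in each library was 2. The exhausted-like share was 62.8% in the single-donor library and 75.8% in the pooled library. The naive-memory list 1.86, the early response list 1.23, the interferon list 1.39, the oxidative phosphorylation list -0.59, the heat shock list 1.06, CD69 2.36 and CD8B -0.72 turned sign in the exhaustion contrast of the single-donor library. EGR1 1.33, HSPD1 1.61, HSPH1 2.19, IFIT2 1.40, KLF2 0.45, MYC 1.82 and TCF7 1.04 turned sign in the exhaustion contrast of the single-donor library. The CD47 antibody 0.029, the CD52 antibody 0.10, the CD49f antibody 0.24, the CD127 antibody 0.17 and the CD101 antibody -0.024 turned sign in the exhaustion contrast of the single-donor library. The cytotoxic list 0.76 crossed 0 in the exhaustion contrast of the pooled library. The cytokine list -0.68 moved in the exhaustion contrast of the pooled library. The cycling list 2.05, CD8A 0.56, FGFBP2 0.11, HSPD1 0.14, ZNF683 -0.96, the CD69 antibody 0.56 and the CD161 antibody -0.48 turned sign in the exhaustion contrast of the pooled library. The heat shock list 0.56 turned sign in the CD69 split of the single-donor library. The cytotoxic list -0.089 turned sign in the CD69 split of the pooled library. The naive-memory list 2.15, the residency list 0.48, the early response list 1.10, CCL4L2 -0.85, CD69 1.99, GNLY 0.22 and GZMH -0.31 turned sign between the libraries. IFNG 0.60 and NELL2 1.15 turned sign between the libraries. The cytokine list 0.50 turned sign in the antibody split of the single-donor library. The CD69 antibody 0.043 moved in the exhaustion contrast of the single-donor library.

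With clusters added one at a time and 10 UMIs per marker, the exhausted-like share was 75.8% in the pooled library. The cytotoxic list 0.76 crossed 0 in the exhaustion contrast of the pooled library. The cytokine list -0.68 moved in the exhaustion contrast of the pooled library. The cycling list 2.05, CD8A 0.56, FGFBP2 0.11, HSPD1 0.14, ZNF683 -0.96, the CD69 antibody 0.56 and the CD161 antibody -0.48 turned sign in the exhaustion contrast of the pooled library. The cytotoxic list -0.091 turned sign in the CD69 split of the pooled library. The residency list 0.60, CCL4L2 -0.47, CXCL13 0.77, FOSB -0.28, GNLY 1.28, GZMK -1.55 and LTB -0.028 turned sign between the libraries. NELL2 0.58 turned sign between the libraries.

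Under the antibody gate, the exhausted-like share was 15.9% in the single-donor library. CD69 0.0024 turned sign in the exhaustion contrast of the pooled library. The cytotoxic list 0.19 crossed 0 in the CD69 split of the single-donor library. The cytotoxic list -0.38 moved between the libraries. The cytokine list reached 0 in the antibody-low split of the single-donor library. The CD69 antibody 0.41 moved in the exhaustion contrast of the single-donor library. The CD69 antibody -0.96 moved in the exhaustion contrast of the pooled library.

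Without the doubted CD8 clusters, the exhausted-like share was 23.5% in the single-donor library and 10.0% in the pooled library. The interferon list 0.62 and HSPD1 0.35 turned sign in the exhaustion contrast of the single-donor library. The cytotoxic list -0.28 moved in the exhaustion contrast of the pooled library. The cycling list 0.43 turned sign in the exhaustion contrast of the pooled library. The CD69 antibody 0.49 moved in the exhaustion contrast of the single-donor library.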

Other observations

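The test of antibody background and the estimate of undetected FOS were chosen only after results had been seen, and the tests on the CD69 split were set before. The antibody test was first made on shares alone and then on counts per cell alone, and both are given here because their answers differ.

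Other CD8 T cells were not uniform. In the pooled library a cluster of 1165 cells had the most CD69 RNA of the CD8 clusters, 1323 CPM (1271 to 1376), with 28.8 CPM of HAVCR2, an inhibitory receptor, and 82.4 CD69 antibody counts per cell. A cluster of 1534 cells had 422 CPM of CD69 RNA (398 to 447), 203 CPM of HAVCR2 and 160 CD69 antibody counts per cell. A cluster of 450 cells led by FGFBP2 and GZMH, genes of circulating-type effector cells, had 269 CPM of CD69 RNA (241 to 300) and 87.8 antibody counts. In the single-donor library the cluster with 3162 CPM of CD69 RNA had a median of 997 UMIs per cell, and the CD8 cluster led by GZMK and CCL4 had 408 CPM and 219 antibody counts.

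The median of the cytokine and chemokine list, of which only chemokines were counted, was higher in exhausted-like CD8 T cells with a CD69 UMI. If any gene detected in a like share of cells split them in the same way, the CD69 split would not stand apart. Its median of 1.01 in the pooled library lay at percentile 100 among splits by 269 control genes, 95% of whose medians lay from −0.71 to 0.52, which argues against that explanation. For a shared immediate early response marked by FOS, the other explanation tested, cells with no FOS UMI were compared, 58 with and 129 without a CD69 UMI, and the median was 0.32 (0.14 to 0.58). This leaves the explanation open. Of the 30 cells with FOS, 12 had 1 UMI. From these, at least 22 of the 187 cells without a FOS UMI (11.8%, a Chao estimate) would hold undetected FOS. Responding cells may thus account for a median above 0. The median of 0.32 also lay within the control range of −0.71 to 0.52, which came from splits that included cells with FOS. It therefore need not be a remaining difference that CD69 marks, and no biological explanation was tested.

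The CD69 antibody was 1.5 times higher in exhausted-like than in other CD8 T cells of the single-donor library, while CD69 RNA was lower. CD69 RNA was 1.82 times lower without the other CD8 cluster of low UMI counts, and was higher in 2 of 14 settings. As shares of antibody counts, the 7 isotype controls had ratios from 1.09 to 2.02, a range that holds the CD69 ratio of 1.5. Per cell the CD69 antibody rose by 299.6 counts (293.9 to 305.3, from 196 to 495) and the isotype controls, which start from few counts, by at most 7.27. Unspecific binding stays open as an explanation, because the measures differ and nothing here shows whether it would add counts or raise them in proportion. The test was limited to the single-donor library after the pooled library had been seen to go the other way, at 0.584, and no biological explanation was tested.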
